A study of Orestias ascotanensis with 42 samples.

How the data were processed

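Small RNA was sequenced from gills, skin and muscle of Orestias ascotanensis, a killifish of the high-altitude Ascotán salt pan in northern Chile. Per the labels' protocols, adult fish were netted on 2 dates, a July and a January collection, with 7 fish each, and the tissues were dissected on site into RNAlater. Small RNA was cut from denaturing polyacrylamide gels, libraries were made with the Illumina TruSeq Small RNA kit and sequenced as paired reads on a NextSeq instrument, and read 1 alone was used, per the labels' protocols. The design text states that each library is a separate biological sample, with no pools and no technical replicates, so the 42 libraries are 14 fish by 3 tissues and p-values measure the spread between fish.

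The season of each library was taken from the treatment label, which reads winter for 7 fish and summer for the other 7. The titles instead carry the word summer for all 42 libraries, followed by N1 or N2. N1 goes with the treatment label winter and N2 with summer in every library, and the direction of each seasonal comparison rests on that label. Season and collection date are the same split. Tissues were paired by fish in the tests of library measures. The main edgeR fits did not include the fish, which was added as a block in an alternative. A batch label from 1 to 7 equals the number of the individual in both collections, which are different fish. What was shared within a batch number is not given in the sources used here, and the number was treated as pairing the collections because the label calls it a batch. The check of that pairing was the correlation, over miRNAs, of the deviations of same-numbered libraries from their group means. It had a median of 0.63 in gills (from -0.37 to 0.77), 0.77 in skin (from -0.43 to 0.87) and 0.14 in muscle (from -0.41 to 0.7), and it exceeded 0.1 in 5, 5 and 4 of the 7 pairs. The same-numbered summer library was the best match of a winter library in only 4, 4 and 2 of 7 cases. The medians alone therefore do not show a batch effect. Between tissues of 1 fish the median correlation was 0.2, 0.13 and 0.17 for the 3 tissue pairs.

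Each library has 1 deposited table of read counts per mature miRNA and precursor, whole numbers that are not normalized, per the file headers. The same tables hold CPM values, scaled to the sum over all entries, per the file headers; they were not used in tests. The column layout is that of the miRDeep2 quantifier. The aligner settings, the miRNA reference release and any filter are not given in the sources used here. The names carry the prefixes of 13 species, so the libraries were counted against miRNAs of several fishes, and no reference genome was used here. A read is counted under every name it matches. There were 3528 entries in 41 tables and 3599 in that of gills winter 1, and the 3527 distinct pairs of mature miRNA and precursor common to all were used. For each of the 1342 names without species prefix, the entry with the highest count was kept; 672 had at least 1 read. Because near-identical names rest on the same reads, names whose counts matched within 5 percent were grouped into read profiles, 339 among the 583 names with at least 42 reads, and results are given per name, with the number of profiles beside the main counts. Members of one family that differ by a base, and variants such as miR-100b-5p beside miR-100, may share reads and are uncertain as separate molecules. The more abundant arm of each list member was tested. The 3p arm of miR-1 is not analysed here.

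The sum over names was 598084 to 27067509 in gills, 11091382 to 36093916 in skin and 18314928 to 57710548 in muscle. Since reads count under several names, this is not the number of reads: with 1 name per profile the totals ran from 201312 to 16822372 per library. Shares of reads below use that second total. Reads carry no molecular identifiers, so the limit of 3 reads that a count of 0 allows covers counting error only. The 95% intervals of log2 ratios rest on the spread between libraries. Within each group of 7, all 126 pairs of libraries were compared by a chi-square test of their counts; 0 pairs were identical, and the lowest chi-square per degree of freedom was 47, so every library was counted as its own replicate.

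Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10 and minimum total of 15, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). Tissues were compared over all 42 libraries with 6 tissue and season groups. Log2 changes between tissues are the second tissue minus the first in the order gills, skin, muscle, averaged over seasons. Seasons were compared within the 14 libraries of a tissue as summer minus winter. Whether the seasonal change differed between tissues was tested as an interaction over all libraries. Standard errors (SE) are the log2 change divided by the square root of F. Measures per library were compared with two-sided exact permutation tests, by sign changes within fish between tissues and over all groupings of 7 against 7 between seasons. Sign changes within batch numbers were added for the seasons after the data had been seen. Normalised CPM in seasonal comparisons are TMM-scaled within a tissue over 1 name per profile.

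Fixed lists of miRNAs were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. P-values were adjusted over the 57 tests between tissues and separately over the 55 between seasons. Fry was run beside camera and adjusted alike. It asks whether list members changed in 1 direction at all, while camera asks whether they changed more than the other names. Fry was not run under shuffled labels. Lists below passed or did not by camera unless fry is named, and fry values are of its directional test. The lists were muscle miRNAs (miR-133, miR-206, miR-499 and the 5p arm of miR-1), epithelial miRNAs (miR-200 family, miR-203, miR-205), the sensory cluster (miR-96, miR-182, miR-183), red blood cell (miR-144, miR-451), white blood cell (miR-142, miR-146, miR-150, miR-155), endothelial (miR-126), neural (miR-9, miR-124, miR-128, miR-132, miR-137, miR-138, miR-153, miR-218, miR-219), pigment cell (miR-204), cartilage and mesenchyme (miR-29, miR-140, miR-199, miR-214), smooth muscle (miR-143, miR-145), liver and gut (miR-122, miR-192, miR-194), gonad and embryo (miR-202, miR-430), osmotic response (miR-21, miR-30, miR-200 family), hypoxia (miR-210, miR-462, miR-731), p53 and DNA damage (miR-15, miR-16, miR-34, miR-192), proliferation clusters (miR-17 to miR-92, miR-106, miR-25), the let-7 family, lipid and insulin (miR-27, miR-33, miR-103, miR-107, miR-122, miR-375) and Hox clusters (miR-10, miR-196). The osmotic response list holds 7 names of the epithelial list, the liver and gut list shares 3 with the p53 list and 1 with the lipid list. Endothelial names are 3 with 1 profile, epithelial names 13 with 9 and white blood cell names 8 with 5. Camera with the preset correlation passed lists readily under shuffled labels, with a median of 14 between tissues and 6 between seasons.

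The design, the lists and the alternatives were chosen before the data were examined, except where the closing section says otherwise. miRNAs are named in the text if they were among the 10 highest in a tissue, the 8 largest changes each way between tissues or the 10 largest between seasons (adjusted p under 0.05, mean CPM of at least 10), a list member, or among the 5 smallest p of the interaction; where under 10 passed between seasons, the 5 smallest p are given as values. Alternatives were totals-only scaling, DESeq2 size factors, no count filter, a mean CPM of at least 10, sums over precursors, robust dispersions, DESeq2 1.42.0, limma voom, a block of fish or batch number, 1 fit for all tissues, and leaving out each library. Totals-only scaling shifted the median log2 change of all names by -1.07 between gills and skin, -3.39 between gills and muscle and -2.28 between skin and muscle. Its shifts between seasons were -0.12 in gills, 0.35 in skin and -0.47 in muscle.

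The tests were tested on simulated counts drawn from the real library sizes and 1 real mean per name over all libraries of a fit. Differences in composition between tissues were therefore not simulated. Many names were changed at once, in gills 95 by 2-fold and 105 by 4-fold among 445. That eases the adjusted threshold, so recovery where few names change, as called in gills and skin, may be lower than the shares given here. False calls made up 1.7 to 5.2% of the calls. Of names changed 2-fold and 4-fold, 85 and 98% were recovered between gills and skin, 83.8 and 100% between gills and muscle, and 84.8 and 97.2% between skin and muscle. Between seasons these were 61.1 and 93.3% in gills (445 names), 62.5 and 92.3% in skin (471 names), and 64.4 and 97% in muscle (427 names). For the interaction they were 29.7 and 83.5% of 525 names. Further computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.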

Results

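Small RNA libraries from gills, skin and muscle of 14 Orestias ascotanensis, a killifish restricted to springs of a high Andean salt pan, gave 42 count tables in 6 groups of 7, a winter and a summer collection for each tissue. The same fish gave all 3 tissues, and different fish were taken in the 2 seasons. The summed count over miRNA names was 598084 to 27067509 per gill library, 11091382 to 36093916 per skin library and 18314928 to 57710548 per muscle library, with the lowest totals in gills summer 4 (598084) and gills winter 2 (1196380). A read counts under every name it matches, so changes are given per name. The number of read profiles stands beside the main counts of names, while counts within lists and under other settings are of names. The seasonal groups follow the treatment label, while the titles carry the word summer for both collections.

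The first question of the design is how the small RNA content differs between tissues. A few miRNAs held most reads. miR-10b, encoded within a Hox gene cluster, made up 19.1 ± 10.3% of gill, 49.9 ± 8.78% of skin and 78.3 ± 2.76% of muscle reads (SD, n = 14 libraries each). Its relative miR-10d-5p held 1.78, 8.80 and 7.08%. miR-181a-5p, known from lymphocyte development, held 11.6 ± 5.06% of gill, 6.50 ± 3.37% of skin and 0.669 ± 0.414% of muscle reads, and miR-143, a smooth muscle miRNA, 5.72, 1.4 and 0.194%. miR-21, a widely expressed stress-responsive miRNA, held 4.12, 2.35 and 0.301%, and let-7a, of a family linked to differentiation, 3.55, 2.04 and 0.563%. The 10 most abundant names of each library together held 49.7 ± 9.34% of the summed counts over names in gills, 76.4 ± 5.78% in skin and 94.9 ± 1.58% in muscle. Skin exceeded gills by 26.7 percentage points in 13 of 14 fish (exact permutation p = 0.000244, adjusted 0.000977 over 12 comparisons), and muscle exceeded gills by 45.2 and skin by 18.5 points in 14 of 14 fish (exact p = 0.000122, adjusted 0.000732, for both). Counted with 1 name per read profile, the shares were 63.2 ± 5.43, 79.7 ± 3.75 and 95 ± 1.55% of reads. The differences were then 16.5, 31.8 and 15.3 points, each in 14 of 14 fish (exact p = 0.000122). The number of names with at least 10 reads was 432 ± 76.4 in gills, 464 ± 26.6 in skin and 425 ± 29.5 in muscle. Muscle minus skin was -38.9, with muscle higher in 2 of 14 fish (exact permutation p = 0.00256, adjusted 0.00769). Skin minus gills (32.1, exact p = 0.22), muscle minus gills (-6.71, exact p = 0.793) and the 3 seasonal comparisons (exact p = 0.448, 0.260 and 0.494) did not pass. These results depend on the limit. With 10 CPM in place of 10 reads, skin minus gills turned to -20, with skin higher in 3 of 14 fish (unadjusted exact p = 0.0166), and muscle minus gills was -119, with muscle higher in 0 of 14 (0.000122). The seasonal differences then became 20.7 in skin (unadjusted exact p = 0.0367) and -23.9 in muscle (0.0291), and that in gills turned from 33.7 to -13.3 (0.31). The seasonal differences in the top-10 share did not pass either (exact p = 0.230, 0.122 and 0.332 in gills, skin and muscle). Sign changes within same-numbered pairs gave exact p = 0.156, 0.0625 and 0.266 for that share. With 1 name per profile the skin share was then lower in summer in 6 of 7 pairs (-3.49 points, unadjusted exact p = 0.0469 within pairs and 0.0857 without). With the 10 CPM limit, the number of names was higher in summer in 7 of 7 skin pairs and 0 of 7 muscle pairs (unadjusted exact p = 0.0156 for each, the smallest that 7 pairs allow). Thinned to equal totals, it was lower in summer in 6 of 7 gill pairs (-13.3, unadjusted exact p = 0.0312).

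**Figure D1:**
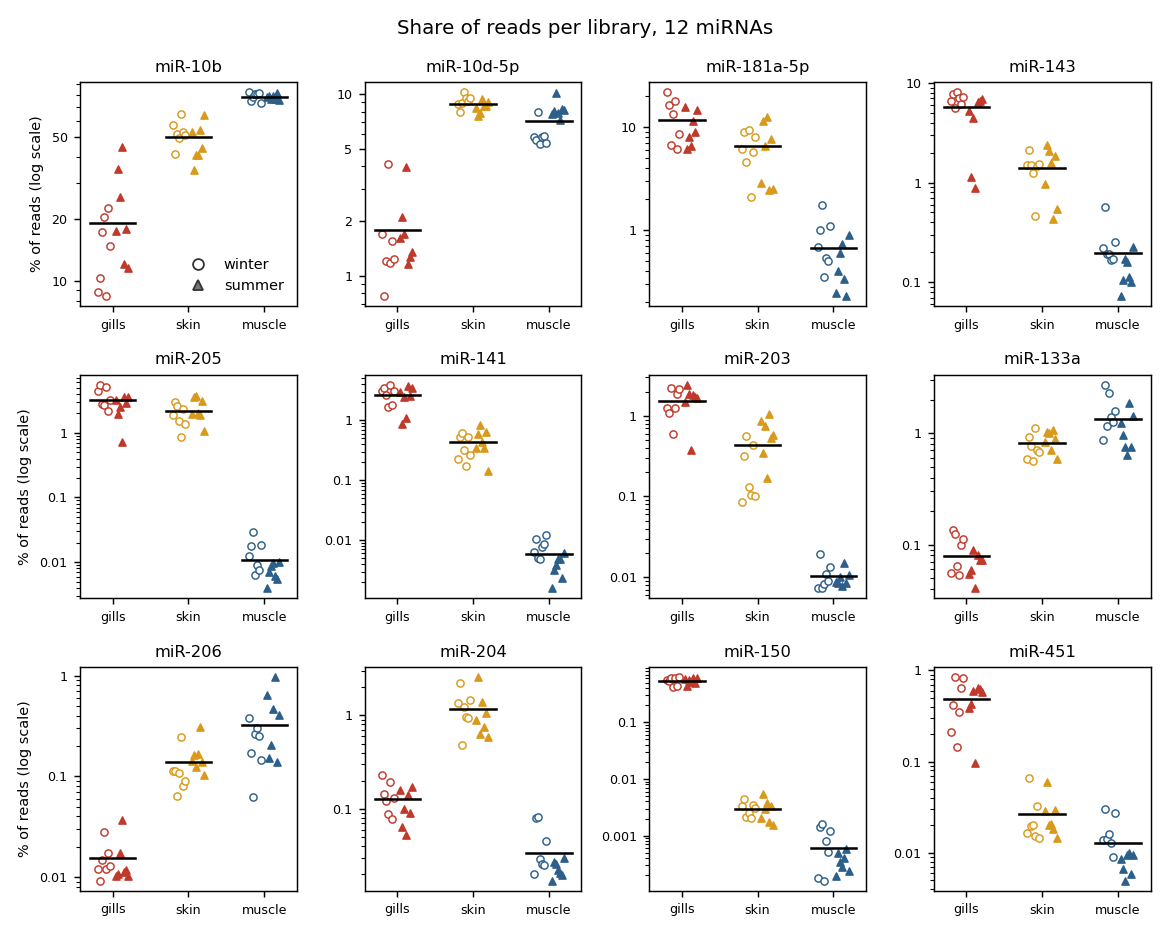
Share of reads (percent, log axis) of 12 miRNAs in each of 42 libraries by tissue, with open circles for winter, filled triangles for summer and a black line at the mean of 14 libraries. miR-10b reached a mean of 78.3% in muscle, while miR-205 stood at 3.16% in gills, 2.20% in skin and 0.0109% in muscle.

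On the first principal component of log2(CPM + 1), which held 79.6% of the variance over 190 profiles, muscle libraries lay at 16.2 to 38.1, gills at -29.4 to -8.36 and skin at -13.1 to 0.992. The second component held 7.92% and separated gills, at 4.9 to 15.7, from skin, at -12.7 to -7.36.

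**Figure D2:**
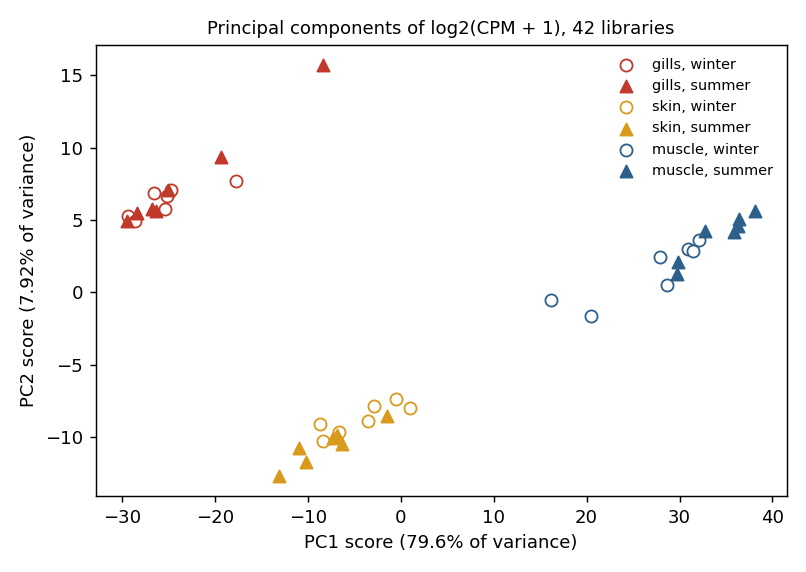
First and second principal component scores of 42 libraries, coloured by tissue, with open circles for winter and filled triangles for summer. Muscle libraries lie above 16.2 on the first component, which holds 79.6% of the variance, and gill and skin libraries part on the second.

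Gills and skin are both body surfaces in contact with the water. miR-150, a lymphocyte miRNA, was 102-fold higher in gills (log2 change to skin -6.68 ± 0.30 SE, n = 14 fish, adjusted p = 2e-23 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). miR-451, abundant in red blood cells, was 10.1-fold higher in gills (-3.34 ± 0.24). miR-375, known from endocrine cells, differed by -3.35 ± 0.22. miR-140-5p, a cartilage miRNA, was also lower in skin (-2.80 ± 0.21). Skin had 85.3-fold more miR-196a (6.42 ± 0.25), which lies in Hox clusters, and 18.9-fold more of the muscle miRNA miR-133a (4.24 ± 0.17). It had 17.0-fold more of miR-204 (4.09 ± 0.28), a pigment cell miRNA, and 16.1-fold more of the muscle miRNA miR-206 (4.01 ± 0.33). These folds are relative to the other miRNAs. With totals-only scaling the higher ones were 5.38, 3.13, 2.99 and 2.96 on the log2 scale.

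Of 525 names tested between gills and skin, 286 in 165 profiles passed (edgeR, 135 higher in skin and 151 lower; 314 at an unadjusted p under 0.05). With totals-only scaling the split was 72 higher and 366 lower, so directions below are relative to the other miRNAs. All 9 muscle miRNAs were higher in skin (9 adjusted over the list alone; median 3.78; camera adjusted p = 9.5e-08, and adjusted p = 0.066 with an estimated correlation). miR-499, of cardiac and slow muscle, was among them at 3.36 ± 0.26. All 7 Hox cluster miRNAs were higher (7 adjusted over the list alone; median 3.05, adjusted p = 3e-06, adjusted p = 0.066 with an estimated correlation). miR-10d-5p differed by 3.05 ± 0.28 and miR-10b by 2.23 ± 0.26. The 3 pigment cell names were higher too (3 adjusted over the list alone; median 4.09, adjusted p = 0.0022, adjusted p = 0.19 with an estimated correlation). In the epithelial list 10 of 13 names were lower in skin and 0 higher, with the same counts adjusted over the list alone (median -1.2, adjusted p = 0.0022, adjusted p = 0.31 with an estimated correlation). miR-200c differed by -1.99 ± 0.24 and miR-141 by -1.80 ± 0.20. miR-205, a keratinocyte miRNA of that list, did not pass (0.30 ± 0.23, and -0.75 with totals only). All 3 red blood cell names were lower in skin (3 adjusted over the list alone; median -2.98, adjusted p = 0.002, adjusted p = 0.066 with an estimated correlation), miR-144 by -2.98 ± 0.26. Of the 5 hypoxia names 4 were lower (4 adjusted over the list alone; median -2.16, adjusted p = 0.014, adjusted p = 0.39 with an estimated correlation). These 4 are miR-731 (-1.12 ± 0.25) and 3 names of its cluster partner miR-462 (-2.35 ± 0.27), which also respond to interferon, while the hypoxia marker miR-210 did not pass (-0.27 ± 0.19). The osmotic response list had 2 names higher, 7 lower and 6 not passing, the same adjusted over the list alone (0 higher and 14 lower with totals only; median -0.29, adjusted p = 0.046, adjusted p = 0.31 with an estimated correlation). The 7 lower names are those it shares with the epithelial list, and the 2 higher ones, miR-30b-5p (0.62 ± 0.26) and miR-30d (0.48 ± 0.16), turned negative with totals only (-0.43 and -0.56).

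The remaining lists did not pass as lists between gills and skin, by camera. By fry the white blood cell (adjusted p = 2.6e-08), smooth muscle (3.4e-07), lipid (9.7e-05) and neural lists (0.0024) did pass, and the others did not. Of 8 white blood cell names 5 were lower in skin (adjusted p = 0.055), miR-155 by -0.87 ± 0.19 and miR-142 by -0.80 ± 0.27. Both smooth muscle names were lower (adjusted p = 0.2), miR-145-5p by -1.56 ± 0.26. Of 26 neural names 11 were higher and 6 lower, and 5 and 10 with totals only (median 0.42, and -0.60 with totals only; adjusted p = 0.5). Examples were miR-219-5p at 2.60 ± 0.49, miR-9 at 1.42 ± 0.21 (0.41 with totals only, which did not pass), miR-137 at -2.29 ± 0.39 and miR-124-3p at -1.86 ± 0.31. Of 13 lipid and insulin names 6 were lower (adjusted p = 0.1), including miR-27b at -1.54 ± 0.15 and the cholesterol-linked miR-33a-5p at -1.07 ± 0.31. Of 20 proliferation cluster names 6 were lower (adjusted p = 0.3). The cartilage list had 1 higher (miR-214, 0.72 ± 0.15, and -0.40 with totals only) and 1 lower of 7 (adjusted p = 0.81). The gonad list had 1 higher of 3, miR-202-5p at 7.07 ± 0.87, so that its median (-0.16) and mean (2.16) differ in sign (adjusted p = 0.75). In the sensory cluster miR-183 was the single name of 3 to pass (0.73 ± 0.26, and -0.33 with totals only; adjusted p = 0.81). With totals only 0 cartilage names were higher and 7 lower, 1 gonad name higher and 2 lower, 0 sensory names higher and 2 lower, and 0 let-7 names higher and 10 lower (edgeR). White blood cell names were then lower in 8, endothelial in 3, liver and gut in 5, lipid in 12, p53 in 14 and proliferation cluster names in 20, with 0 higher in each list (edgeR). The counts of these lists with the main scaling were the same adjusted over the list alone, except for let-7 and p53. The p53 list had 2 lower names of 14 and 0 adjusted over the list alone (adjusted p = 0.69). The let-7 family had 1 higher of 10, let-7d-5p at 0.46 ± 0.20 (-0.57 with totals only), and 0 adjusted over the list alone (adjusted p = 0.91). By edgeR 0 of 3 endothelial names (miR-126-5p 0.00 ± 0.21; adjusted p = 0.88) and 0 of 6 liver and gut names passed, nor did any at an unadjusted p under 0.05 (adjusted p = 0.75; median -0.22 against a test pointing up).

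Between gills and muscle, miR-141, of the epithelial miR-200 family, was 57.6-fold lower in muscle (-5.85 ± 0.23, n = 14 fish, edgeR adjusted p = 1.2e-25), miR-205 34.6-fold lower (-5.11 ± 0.27) and miR-150 120-fold lower (-6.91 ± 0.31). miR-206 was 153-fold higher (7.26 ± 0.39) and miR-133a 132-fold higher (7.04 ± 0.20, adjusted p = 3.7e-31), both of which act in skeletal muscle differentiation. miR-219-5p, known from oligodendrocytes, was 169-fold higher (7.40 ± 0.49), miR-9, a neuronal miRNA, 84.7-fold higher (6.40 ± 0.26) and miR-10b 33.5-fold higher (5.07 ± 0.30). These folds depend on the scaling, as totals only moved the median of all names by -3.39. With it the log2 changes were 3.93 for miR-206, 3.64 for miR-133a, 4.13 for miR-219-5p, 3.01 for miR-9 and 1.68 for miR-10b. Those of miR-141, miR-205 and miR-150 were -9.34, -8.68 and -10.37.

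A total of 402 of 525 names in 229 profiles passed between gills and muscle (edgeR, 197 higher in muscle and 205 lower; 409 at an unadjusted p under 0.05), against 48 higher and 442 lower with totals-only scaling. The muscle list had 9 of 9 names higher, and 4 with totals only (median 4.06, adjusted p = 4.7e-05 by camera, adjusted p = 0.16 with an estimated correlation), although miR-499 (2.90) and miR-133c (3.30) turned to -0.45 and -0.11 with totals only. All 7 Hox cluster names were higher, and 6 with 1 lower with totals only (median 5.07, adjusted p = 0.00014, adjusted p = 0.16 with an estimated correlation), including miR-196a at 6.36 ± 0.24; miR-10c at 2.38 turned to -1.02 with totals only. Of 26 neural names 23 were higher and 2 lower, and 7 and 13 with totals only (median 3.03, and -0.28 with totals only; adjusted p = 5.7e-06, adjusted p = 0.066 with an estimated correlation). All 13 epithelial names were lower (median -5.01, adjusted p = 2.8e-08, adjusted p = 0.066 with an estimated correlation). All 8 white blood cell names were lower too (median -2.79, adjusted p = 0.00061, adjusted p = 0.19 with an estimated correlation), with miR-142 at -2.83 ± 0.29 and miR-146a-5p, an inflammation-linked miRNA, at -2.75 ± 0.21. Each of these 5 lists had the same counts adjusted over the list alone. Of 5 hypoxia names 4 were lower, and 5 adjusted over the list alone (median -4.66, adjusted p = 0.0074, adjusted p = 0.34 with an estimated correlation). miR-731 differed by -3.70 ± 0.27. The osmotic response list had 4 names higher and 9 lower of 15, and 4 and 10 adjusted over the list alone (0 and 15 with totals only; median -0.80, adjusted p = 0.019, adjusted p = 0.23 with an estimated correlation). The lower names are the 7 shared with the epithelial list and miR-21 under 2 names (-0.80 ± 0.14), and the higher ones are miR-30 names such as miR-30a-5p (1.57 ± 0.24), which turned to -1.78 with totals only.

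Lists that did not pass by camera between gills and muscle still held changed members. Of these the red blood cell (adjusted p = 1.8e-15), sensory cluster (1.7e-12), lipid (6.1e-09) and smooth muscle lists (6.3e-07) passed by fry. So did the cartilage (fry adjusted p = 0.00043), pigment cell (0.0018), proliferation cluster (0.0027) and endothelial lists (0.049), while the others did not. All 3 red blood cell names were lower in muscle (adjusted p = 0.071), miR-451 by -2.35 ± 0.23, and both smooth muscle names (adjusted p = 0.5), miR-143 by -1.86 ± 0.24. All 3 pigment cell names were higher, miR-204 at 1.12 ± 0.25 (-2.41 with totals only; adjusted p = 0.57), and all 3 sensory cluster names, miR-183 at 2.98 ± 0.28 (-0.24 with totals only; adjusted p = 0.19). Proliferation cluster names were lower in 14 of 20 (adjusted p = 0.12), miR-92 by -2.10 ± 0.30. Lipid and insulin names were lower in 8 of 13 with 1 higher (adjusted p = 0.18), miR-375 by -5.81 ± 0.25. Cartilage names were lower in 4 of 7 and higher in 1 (adjusted p = 0.46), miR-29a, which targets collagen genes, by -1.21 ± 0.22. The let-7 family had 4 higher of 10 (adjusted p = 0.75), let-7d-5p at 1.72 ± 0.20 (-1.69 with totals only). The p53 list had 1 higher and 3 lower of 14 (adjusted p = 0.75). These counts were the same adjusted over the list alone. With totals only 0 pigment names were higher and 3 lower, 0 sensory and 2 lower, 0 cartilage and 7 lower, 0 lipid and 13 lower, 0 let-7 and 10 lower, 0 p53 and 14 lower, and 0 liver and gut and 6 lower (edgeR). Endothelial names were then lower in 3, gonad names in 2 and proliferation cluster names in 20, with 0 higher (edgeR). Of 6 liver and gut names 1 was higher, miR-122 at 1.75 ± 0.78 (-1.86 with totals only), and 0 adjusted over the list alone (median -0.96 against a test pointing up, adjusted p = 0.81). By edgeR 0 of 3 endothelial (adjusted p = 0.69) and 0 of 3 gonad names passed, nor did any at an unadjusted p under 0.05 (median -0.41, mean 0.36, adjusted p = 0.99).

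Between skin and muscle the keratinocyte miRNA miR-205 was 42.7-fold lower in muscle (-5.42 ± 0.28, n = 14 fish, edgeR adjusted p = 5.1e-21), miR-141 16.5-fold lower (-4.05 ± 0.21) and miR-203, which restrains epidermal stem cells, differed by -3.06 ± 0.26. miR-204 was 7.8-fold lower in muscle (-2.96 ± 0.26). Muscle had 31.6-fold more miR-9 (4.98 ± 0.24, adjusted p = 3.7e-22), 9.52-fold more miR-206 (3.25 ± 0.32), 7.17-fold more miR-10b (2.84 ± 0.27) and 6.99-fold more miR-133a (2.81 ± 0.16). Totals only moved the median of all names by -2.28. The log2 changes were then 2.61 for miR-9, 0.97 for miR-206, 0.47 for miR-10b and 0.51 for miR-133a (edgeR adjusted p = 0.004 and 0.012 for the latter pair). Those of miR-205, miR-141, miR-203 and miR-204 were -7.94, -6.49, -5.44 and -5.4.

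Of the 525 names 352 in 200 profiles passed between skin and muscle (edgeR, 170 higher in muscle and 182 lower; 364 at an unadjusted p under 0.05), against 43 higher and 433 lower with totals-only scaling. All 13 epithelial names were lower (median -3.92, adjusted p = 6.6e-09 by camera, adjusted p = 0.066 with an estimated correlation). Neural names were higher in 23 of 26 and lower in 3, and 17 and 8 with totals only (median 3.10, adjusted p = 2.8e-08, adjusted p = 0.066 with an estimated correlation), including miR-124-3p, a neuronal miRNA, at 3.26 ± 0.32 and miR-137 at 3.97 ± 0.40. White blood cell names were lower in 7 of 8 (median -2.02, adjusted p = 0.0024, adjusted p = 0.25 with an estimated correlation) and pigment cell names in 3 of 3 (median -2.96, adjusted p = 0.022, adjusted p = 0.33 with an estimated correlation). Hypoxia names were lower in 4 of 5 (median -2.51, adjusted p = 0.021, adjusted p = 0.42 with an estimated correlation), miR-462 by -2.51 ± 0.27. The osmotic response list had 4 higher and 9 lower of 15, and 0 and 15 with totals only (median -0.82, adjusted p = 0.019, adjusted p = 0.23 with an estimated correlation), the higher ones again miR-30 names, such as miR-30c-5p at 1.42 ± 0.29 (-0.84 with totals only). Counts adjusted over the list alone were the same for these 6 lists. With 1 name per read profile 14 lists passed between tissues against 20, the muscle list between skin and muscle being added. The osmotic response list no longer did in any tissue pair (camera adjusted p = 0.18, 0.19 and 0.23), nor did hypoxia between gills and skin (0.058) and skin and muscle (0.083), or white blood cell (0.069) and pigment cell miRNAs (0.091) between skin and muscle.

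The muscle list did not pass between skin and muscle (5 of 9 names higher, median 1.01, and -1.25 with totals only; adjusted p = 0.076), nor did the Hox cluster list (4 of 7 higher, median 0.98, and -1.33 with totals only; adjusted p = 0.1), and miR-133c (1.01) and miR-10c (0.98) turned to -1.25 and -1.33 with totals only. All 3 sensory cluster names were higher (adjusted p = 0.12), miR-182 at 1.37 ± 0.24 (-0.99 with totals only). Of the red blood cell names 1 of 3 was higher, miR-451 at 0.98 (-1.4 with totals only; adjusted p = 0.63), and of the smooth muscle names 1 was higher and 1 lower (adjusted p = 0.97). Cartilage names were higher in 1 and lower in 3 of 7 (adjusted p = 0.57), miR-140-5p at 0.92 ± 0.20 (-1.30 with totals only). Lipid names were higher in 2 and lower in 7 of 13 (adjusted p = 0.57), and let-7 names higher in 3 and lower in 2 of 10 (adjusted p = 0.75), let-7e at 0.78 ± 0.21 (-1.58 with totals only) and let-7i at -0.48 ± 0.17. Of the gonad names 1 of 3 was lower, miR-202-5p by -5.12 (adjusted p = 0.75). These counts were the same adjusted over the list alone. The p53 list had 3 higher and 1 lower of 14, and 1 and 1 adjusted over the list alone (adjusted p = 0.97), and proliferation clusters had 6 lower of 20, and 5 adjusted over the list alone (adjusted p = 0.34). By edgeR 0 of 3 endothelial (adjusted p = 0.71) and 0 of 6 liver and gut names (adjusted p = 0.97) passed, nor did any at an unadjusted p under 0.05. With totals only the muscle list had 2 higher and 5 lower, the Hox list 2 and 5, lipid names 0 and 12, let-7 0 and 10, the p53 list 0 and 14, cartilage 0 and 7, red blood cells 0 and 3, and the sensory and smooth muscle lists 0 and 2 each (edgeR). Endothelial names were then lower in 3, liver and gut in 5, gonad in 3 and proliferation cluster names in 20, with 0 higher (edgeR). Of the lists in this paragraph, the sensory cluster (adjusted p = 1.9e-10), muscle (1.5e-08) and Hox cluster lists (3.4e-07) passed by fry. The cartilage (fry adjusted p = 0.0088), lipid (0.0088) and red blood cell lists (0.012) did too, and the others did not.

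The second question is what differed between the winter and summer collections within each tissue. Gill libraries held 1196380 to 12778743 counts in winter (median 4947715) and 598084 to 27067509 in summer (median 20423114). In gills, miR-26d-5p alone passed, with 3.91-fold less in summer (-1.97 ± 0.32, n = 7 and 7 fish, edgeR adjusted p = 0.0082; normalised CPM 91.2 ± 36.8 in winter and 26.9 ± 16.3 in summer). It is a low-abundance name of the miR-26 family. Of 460 names in gills 29 had an unadjusted p under 0.05, and 2 names passed with the batch number as a block, 6 with DESeq2 and 2 with limma voom. The call was lost without gills summer 3, 5 or 7 (0 names in each case) and without minor names, those under 5 percent of the leading name of their number over all libraries (0 by edgeR, 28 at an unadjusted p under 0.05). The next smallest p values belonged to miR-31-5p (2.09 ± 0.46, adjusted p = 0.078), miR-24a (-0.43 ± 0.12, 0.25), miR-100b-5p (-2.35 ± 0.68, 0.25) and miR-99 (0.55 ± 0.18, 0.39), all edgeR values that did not pass. Of these miR-100b-5p passed with the batch number as a block (-3.58), with limma voom (-3.60), with DESeq2 (-2.87) and without gills summer 2 (-4), and miR-24a with DESeq2 (-0.36). miR-31-5p passed in 8 settings, including DESeq2 (2.14), no filter (2.16), 1 name per profile (2.12), 1 fit of all tissues (2.20) and without winter 4 (2.64) or summer 4 (2.19). miR-20b, chosen after its values were seen, was below the count filter in gills and passed in 12 settings that tested it (4.39 with no filter).

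In skin 3 of 477 names passed (edgeR, 50 at an unadjusted p under 0.05). miR-31-5p, of a family active in keratinocytes, was 37.5-fold higher in summer (5.23 ± 0.53, adjusted p = 1.5e-05; normalised CPM 1.54 ± 0.863 and 60.6 ± 32.0, n = 7 each), and is a minor name at 6.72% of miR-31 in skin. miR-100b-5p fell by 2.73 on the log2 scale (SE 0.52, adjusted p = 0.014; 107 ± 39.8 to 16.1 ± 18.7 normalised CPM). The Hox cluster name miR-196d, with a mean CPM under 10, fell by 2.30 (SE 0.36, adjusted p = 0.0025). With the batch number as a block 8 names in 4 profiles passed. The added ones were all names of miR-142 (from -0.75 to -0.73, edgeR adjusted p = 0.04). With DESeq2 7 passed, and without minor names 0 did (edgeR, 41 at an unadjusted p under 0.05). Without skin winter 2 miR-31-5p alone passed, and miR-196d also lost its call without winter 3 or 7.

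**Figure D3:**
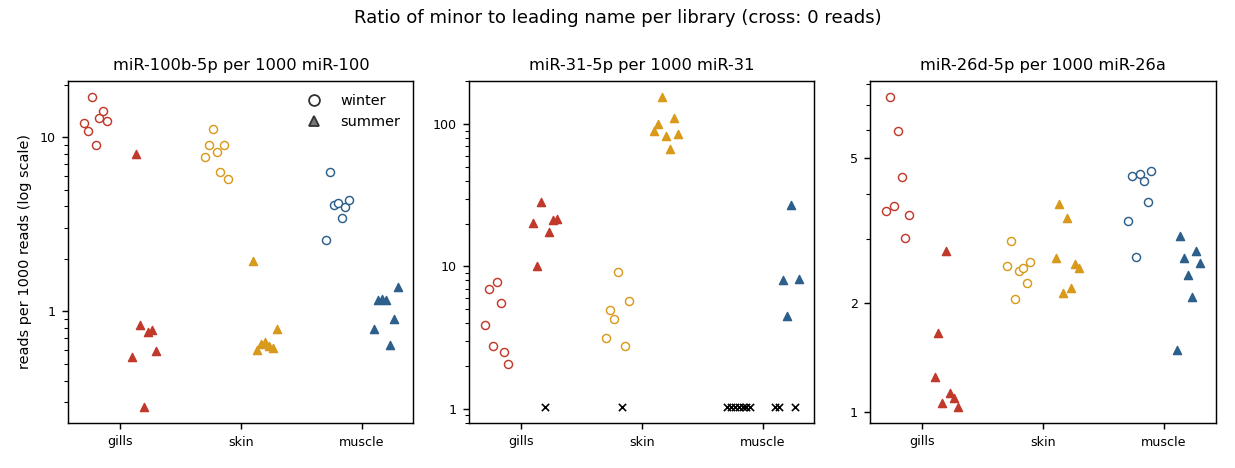
Reads of 3 minor names per 1000 reads of the leading name of their number (log axis) in each library by tissue, with open circles for winter, filled triangles for summer and crosses for 0 reads. miR-31-5p per 1000 miR-31 had means of 4.29 in winter and 98.5 in summer skin, and miR-100b-5p per 1000 miR-100 had 8.17 and 0.844.

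In muscle miR-99, miR-100, let-7e and let-7d-5p, of families that are partly encoded together in vertebrate genomes, were higher in summer. miR-100 rose 4.23-fold (2.08 ± 0.29, edgeR adjusted p = 9.5e-05), from 5335 ± 1807 to 22920 ± 7740 normalised CPM (n = 7 each), and the lowest summer library (14220) lay above the highest winter library (8201). miR-99 rose 3.85-fold (1.94 ± 0.27), let-7e by 1.49 ± 0.26 and let-7d-5p by 1.22 ± 0.26 on the log2 scale. The neuronal miR-9 rose by 0.76 ± 0.24 and miR-129 by 1.09 ± 0.25, calls that were lost with totals only (0.17 and 0.60). miR-142, a leukocyte miRNA, fell by 1.92 (SE 0.54, adjusted p = 0.024), from 70.4 ± 86.0 to 18.9 ± 10.4 normalised CPM. miR-101a fell by 1.12 (SE 0.25), miR-148 by -1.10 ± 0.24, miR-2184 by -1.36 ± 0.29 and the fibroblast miRNA miR-199a-5p by -0.88 ± 0.18. miR-26d-5p fell by 1.0 (SE 0.26, adjusted p = 0.014), at a mean of 3.44 CPM.

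A total of 59 of 427 names in 31 profiles passed in muscle (edgeR, 28 higher and 31 lower in summer; 115 at an unadjusted p under 0.05), against 17 higher and 75 lower with totals-only scaling. The count was 39 without muscle winter 7 and 38 without summer 2. Without winter 7, whose miR-142 stood apart (261 against 14.4 to 61.3 normalised CPM), the miR-142 change was -1.07 and did not pass, nor did it pass without summer 1, 2 or 3, with the batch number as a block (-1.45) or with voom (-1.52). The abundant muscle names miR-10b (0.43 ± 0.28, and 0.00 with totals only), miR-133a (-0.08) and miR-206 (1.17 ± 0.42, edgeR adjusted p = 0.073) did not pass.

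**Figure D4:**
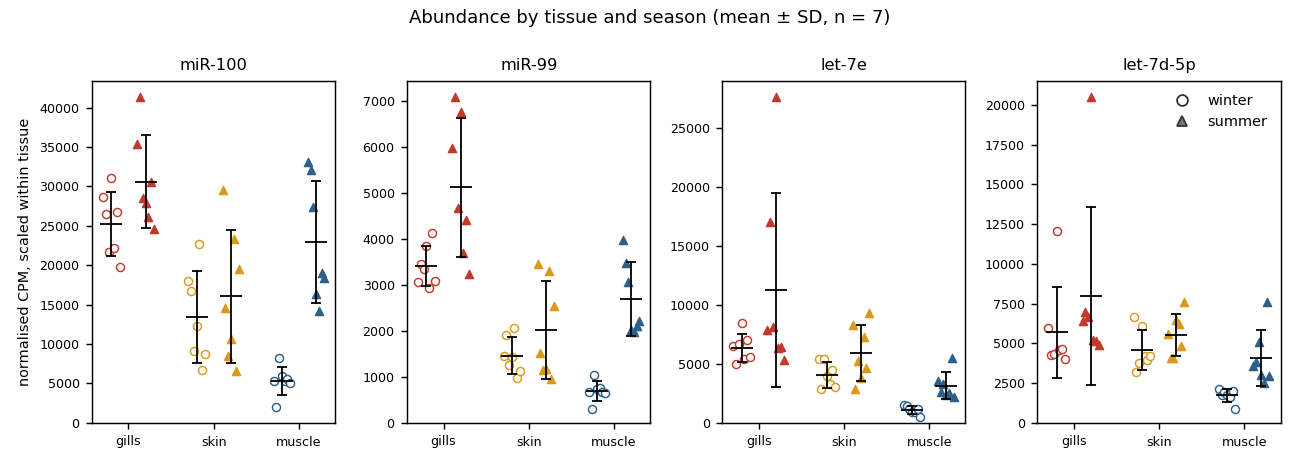
Normalised CPM, scaled within tissue, of miR-100, miR-99, let-7e and let-7d-5p in winter (open circles) and summer (filled triangles) libraries, with the mean ± SD of 7 libraries. In muscle miR-100 lies at or below 8201 in winter and at or above 14220 in summer, and in gills winter 4 and summer 4 stand apart for let-7d-5p (12100 and 20500).

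Among the fixed lists 5 of 55 seasonal tests passed by camera with the preset correlation, and 0 of 55 with an estimated one. By fry these 5 did not pass, with adjusted p = 0.31 for let-7 in muscle, 0.085 for Hox and 0.57 for epithelial names in skin. The fry adjusted p was 0.35 for p53 and 0.68 for liver and gut names in gills. The let-7 family rose in muscle as a list (2 of 10 names up, the same adjusted over the list alone; median 0.51, and 0.00 with totals only; adjusted p = 0.0037, adjusted p = 0.87 with an estimated correlation). The Hox cluster list was lower in summer skin (1 of 7 names down, and 2 adjusted over the list alone; median -0.43, adjusted p = 0.0037, adjusted p = 0.38 with an estimated correlation), with miR-10c at -0.96 ± 0.26 (edgeR adjusted p = 0.19). The epithelial list was higher in summer skin with 0 of 13 names passing by edgeR, also adjusted over the list alone, and 3 at an unadjusted p under 0.05 (median 0.28, adjusted p = 0.017, adjusted p = 0.87 with an estimated correlation, and 0.054 with 1 name per profile). In gills the p53 list (0 of 14 names; median 0.08, and -0.06 with totals only) and the liver and gut list (0 of 6; median -0.06, mean 0.00 and a test pointing up) had adjusted p = 0.0037, with adjusted p = 0.38 and 0.87 with an estimated correlation, and by edgeR 0 of their names passed adjusted over the list alone, and 1 and 0 at an unadjusted p under 0.05. With the batch number as a block 2 further lists passed in skin, white blood cells (median -0.46, adjusted p = 0.067 without and 0.025 with the block) and let-7 (median 0.23, adjusted p = 0.062 and 0.021).

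In muscle other lists had single members that passed while the list did not. White blood cell names were lower in 3 of 7 (median -0.68, adjusted p = 0.23). These 3 are names of miR-142, 1 read profile, whose call was lost without winter 7, with voom and with the block. Of the neural names 3 of 23 were higher, the names of miR-9 (0 higher and 6 lower with totals only), against a list median of -0.57 (adjusted p = 0.61). A red blood cell name, miR-451, fell by 0.62 (SE 0.20; 1 of 3, adjusted p = 0.71), and 1 of 6 cartilage names was lower (adjusted p = 0.23). The p53 list had miR-15e-5p higher (2.93 ± 0.33, at a mean of 0.826 CPM, 1 of 13, camera adjusted p = 0.3). The osmotic list had miR-21a-5p higher (0.86 ± 0.27, 1 of 15, 0 higher and 2 lower with totals only, and 0 adjusted over the list alone, camera adjusted p = 0.92). Adjusted over the list alone, 1 of 3 sensory cluster names was higher in muscle, and 2 of 9 muscle miRNAs in skin (median 0.04, adjusted p = 0.29), where 0 passed over all names by edgeR.

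The third question is whether the seasonal change differed between tissues. It did for 14 of 525 names in 9 profiles (edgeR interaction, 64 at an unadjusted p under 0.05). miR-100 changed by 2.19 ± 0.30 in muscle, with 0.36 ± 0.29 in gills and 0.22 ± 0.29 in skin (adjusted p = 0.0016; muscle against gills 0.0079 and against skin 0.0021). miR-99 changed by 2.05 ± 0.27 in muscle, with 0.65 ± 0.26 in gills and 0.42 ± 0.26 in skin (adjusted p = 0.0055). miR-31-5p, with 5.22 in skin and 2.20 in gills, differed between these tissues (edgeR adjusted p = 0.0052), as did miR-26d-5p, with 0.06 in skin and -1.81 in gills (0.0037). miR-100b-5p, with -2.80 in skin and 0.32 in muscle, differed between that pair (0.018). The interaction held for 5 names without minor names.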

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

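The tests on minor names and library differences, those on the mislabelled library and the outlier test of the 4 plotted miRNAs were chosen after their results had been seen; the splits of the samples and the tests on muscle were chosen before.

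In summer muscle miR-99, miR-100, let-7e and let-7d-5p were higher, and the seasonal change of miR-100 (edgeR interaction, adjusted p = 0.00156) and miR-99 (0.00554) differed between tissues, as it did for 14 names in all. A few miRNAs taking most of the counts are argued against as the whole cause, since with totals-only scaling the 5 profiles kept a median change of 1.06 and 5 were called, and miR-10b held 78.6 ± 3.5% of winter and 78.0 ± 2.02% of summer reads (SD, n = 7, exact permutation p = 0.69). After thinning to equal totals 5 of the 5 profiles were still called (miR-100 at 2.18). These abundant profiles keep many counts at the lowest muscle total, so thinning could hardly remove their calls. It therefore shows that the changes stand at equal depth, but weighs little as a test of depth. More skin or gill tissue in summer muscle would raise the epithelial miRNAs, whose median change was -0.31 with 0 of 12 called (edgeR). That does not bear on more non-muscle tissue in winter muscle, a limit on the names lower in summer, which was not tested. On the first principal component muscle winter 7 (16.2) and winter 2 (20.4) lay nearer to skin and gills than the summer muscle libraries (29.8 to 38.1). The other winter muscle libraries overlapped the summer ones. Season remains open and may be the source, but it was not tested apart from the collection date, which is the same split of the fish.

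Minor names, under 5 percent of the leading name of their number over all libraries (miR-31-5p reached 6.72% in skin), made up every seasonal call of the main fit in gills and skin. Reads of the leading name counted under the minor name at a fixed rate would keep the ratio of the pair constant. It differed between seasons in each of the 4 called pairs (largest exact permutation p = 0.00058, n = 7 and 7). These pairs were chosen because the minor name was called in the same libraries, where the leading name was not. A shifted ratio was therefore likely beforehand, and its p-value is no independent evidence against a fixed rate. A library or run difference acting on the minor name alike in all tissues is argued against for miR-100b-5p, which changed by -2.80 in skin and 0.32 in muscle (edgeR adjusted p of the difference = 0.018), and miR-26d-5p (-1.81 in gills, 0.06 in skin, 0.0037), but cannot be told apart from season for miR-31-5p, which was higher in summer in skin (5.22) and gills (2.20, p of the difference 0.0052) and had 0 winter and 5 summer reads in muscle, too few to tell, and miR-196d (0.089). A shared shift of the ratio is argued against for miR-26d-5p, with 0.13 in skin (95% interval -0.16 to 0.41) against -1.67 in gills and -0.71 in muscle, and stays open for miR-100b-5p (-3.76, -3.37 and -2 in 3 tissues, in muscle with a rise of miR-100), for miR-31-5p (2 tissues) and for miR-196d (1). For miR-31-5p the muscle shift (0.69, from -0.39 to 1.76, against 4.60 in skin) met the bound that would have argued against it, and it is open only because a minimum of 10 expected reads was added after that value was seen (2.9 in muscle), while season, or a sequence variant that differs between the fish, stays possible and untested.

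Muscle gave 59 seasonal calls and gills 1. Lower depth in gills is argued against as the whole cause, since muscle thinned to the gill totals still gave 44 calls among 340 names. A larger spread between gill libraries is argued against too, as the median SE in gills was 0.889 times that in muscle (0.289 and 0.325 over 206 profiles). A tissue difference in the response to season may remain, and is a hypothesis found and tested on the same libraries. The difference in the number of calls was not itself tested.

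Other splits of the fish tell whether chance can be excluded. For tissues, labels shuffled within fish gave as many calls in 1 of 100 splits, the real one, so chance can be excluded for gills and skin (286, highest other 192), gills and muscle (402, highest other 108) and skin and muscle (352, highest other 144). For the seasons it can be excluded in muscle (59; 1 of 100 splits, highest other 25; 1 of the 64 that swap seasons within a batch number, highest other 19) and for the interaction (14; 1 of 100, highest other 2; 1 of 64, highest other 1). In gills (1 call) 1 of 100 splits gave as many, with a highest other of 0, and 2 of 64, with a highest other of 1. That count only asks whether any name crosses the threshold, and it fell to 0 without summer 3, 5 or 7. Chance is therefore not called excluded in gills. In skin (3 calls) 4 of 100 splits gave as many, and 1 of 64 with a highest other of 1. The highest of the 100 in skin gave 29, several times the real count, while the median of the others was 0. A split other than the season can thus give more calls in skin. Whether a structure of the skin samples lay behind that 1 split was not tested. That split gave 0 calls in gills and muscle (edgeR) and kept 4 of 7 same-numbered pairs together, numbers 2 to 5, whose skin libraries had correlations of 0.77 to 0.87. Whether the batch number contributed to these 29 calls stays open, as the next splits, with 6 pairs together, gave 3 calls each. The blocked fit in skin gave 8. The 64 splits within batch numbers part all 7 pairs, as the real one does. Between tissues 20 lists passed by camera (9 of 100 splits as many, median of the others 14, highest 24). Shuffling labels within fish leaves the tissue differences in the data, as variation that members of a list share. Camera with the preset correlation passes lists on such variation. These splits do not exclude chance for the tissue lists, but they can hardly decide the question either way. Between seasons 5 lists passed, and chance cannot be excluded for them (71 of 100 splits as many, median of the others 6, highest 16, and 29 of 64, median 4, highest 11). With the preset correlation lists thus passed readily under shuffled labels. Their number cannot tell whether a given list differs, and it does not bear on the edgeR calls of the members.

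Single libraries stood far from the other 6 of their group in 12 of 66 groups and measures tested, by a Dixon test of the gap to the nearest library. Its rate of about 1 in 20 by chance holds for normally distributed values. Most measures were untransformed normalised CPM of names picked for a seasonal change or for the plots, which need not meet that. The number that stood apart is therefore no evidence of an excess over chance. Gills summer 4, the shallowest library, had 241 names with at least 10 reads, against 414 to 517. let-7d-5p stood at 12100 normalised CPM in gills winter 4 (others 4030 to 5940), 20500 in gills summer 4 (4920 to 6960) and 883 in muscle winter 7 (1600 to 2110). let-7e stood at 5470 in muscle summer 6 (2180 to 3580). miR-100b-5p stood at 331 in gills summer 2 (7.82 to 23.7) and 57.5 in skin summer 1 (4.05 to 15.4). A wholly mislabelled winter library is argued against for gills summer 2, with 0 of 3 minor name ratios in the winter range. Its miR-100b-5p ratio of 7.99 per 1000 reads lay between winter (8.98 to 17.1) and the other summer gill libraries (up to 0.829). The miR-31-5p ratio was 10.1 (winter up to 7.79) and that of miR-26d-5p 1.65 (winter from 3.01). A mixture of winter and summer material was not tested. miR-101a stood at 1100 in muscle winter 2 (415 to 707). miR-142 stood at 261 in muscle winter 7 (14.4 to 61.3) and 40.3 in muscle summer 4 (8.67 to 21.1). miR-26d-5p stood at 169 in gills winter 2 (59.2 to 94.7) and 62.6 in gills summer 4 (17.7 to 30.4).

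The table of gills winter 1 holds entries of the species prefix hhi that the comparisons do not use. Of 22 such entries 15 have reads, above the limit of 3 that a count of 0 allows, and the highest, a miR-21 entry, has 85149.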

How the results depend on the processing

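The alternatives with 1 name per read profile, zebrafish names, no minor names, a doubted library left out or library measures paired by batch number were added after the data had been seen. For the 43 named changes carried through the alternatives, direction and threshold held in 753 settings, 10 lost the call, 6 gained it and 0 reversed. Among all named changes past the threshold, the sign turned with totals only for 6 of 102 between gills and skin, 34 of 146 between gills and muscle, 28 of 127 between skin and muscle and 0 between seasons. A further 12, 7 and 6 of these tissue changes kept their sign but no longer passed. The same held for 8 of 33 between seasons in muscle. Among the 43, calls were lost for miR-142 in muscle (-1.518 with voom, -1.446 with the block, -1.07 without winter 7, and -1.795, -1.791 and -1.684 without summer 1, 2 or 3), for miR-26d-5p in gills (-1.855, -1.844 and -1.838 without summer 3, 5 or 7) and for miR-100b-5p in skin (-2.656 without winter 2). Outside the 43, miR-196d lost its skin call without winter 2, 3 or 7. Calls were gained for miR-100b-5p in gills (-2.868 with DESeq2, -3.597 with voom, -3.579 with the block and -3.996 without summer 2), miR-24a in gills (-0.36) and miR-10c in skin (-0.938), both with DESeq2.

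Between gills and skin 438 names passed with totals only. A mean CPM of at least 10 gave 157, 230 and 223 names for gills and skin, gills and muscle, and skin and muscle, 1 name per profile gave 159, 218 and 194, and zebrafish names 57, 88 and 78, in each case with fewer names tested. The gill season count of 1 became 6 with no filter, 4 with sums over precursors, 2 per profile, 0 without minor names (28 at an unadjusted p under 0.05 by edgeR), 6 with DESeq2, 2 with voom, 2 with the block of batch number, 6 in 1 fit of all tissues and 4 without winter 1 and summer 4. The skin count of 3 became 0 without minor names (41 at an unadjusted p under 0.05 by edgeR), 7 with DESeq2, 8 with the block and 9 in 1 fit. With zebrafish names alone 1 passed in gills and 2 in skin. Among them miR-181c-5p, not called in the main fit, was higher in summer in gills (1.62, edgeR adjusted p = 0.0016) and skin (3.66, 3.5e-06). The other skin call was miR-196d (-2.34, 0.00037), and miR-26d-5p was not among the gill calls. The muscle count of 59 became 92 with totals only, 31 per profile and 12 with zebrafish names, and was 65 with the block. The interaction fell to 4 names with zebrafish names and 5 without minor names. With an estimated correlation 0 lists passed between tissues or seasons by camera, and with both arms 11 passed between seasons. The block of fish gave 283, 404 and 362 calls between tissues and 14 for the interaction, and in the list tests 20 and 7. Beyond the named changes, miR-142 in skin and the 2 skin lists, blocking changed no other call given in the text.

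Leaving out 1 library gave 0 to 4 calls in gills (0 without summer 3, 5 or 7; 2 without summer 2; 3 without winter 1, 2, 3, 5, 6 or 7; 4 without winter 4 or summer 4), 1 to 3 in skin (1 without winter 2) and 38 to 78 in muscle (38 without summer 2, 39 without winter 7). The difference in detected names became 20.71 (10 CPM) and 22.86 (thinned) between seasons in skin, -23.86 and -22 in muscle, and turned from 33.71 to -13.29 in both settings in gills, where neither passed unpaired. It became -20 and -30.07 between gills and skin, -119 and -121.8 between gills and muscle and -99 and -91.71 between skin and muscle. The share of the 50 most abundant names differed by -1.795 points between seasons in skin and 0.4865 in muscle. Except where fewer names, or fewer libraries, were tested, the cause was not tested. Gills have the lowest totals, which limits rare names there.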

Other observations

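The correlation of seasonal changes between tissues was tested as fixed before its result was seen; miR-196b-5p, miR-7, miR-338 and miR-214-5p were singled out after their values had been seen.

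Several miRNAs outside the lists also differed between tissues. miR-181a-5p was lower in muscle than in gills (-1.07 ± 0.29 SE, n = 14 fish), and miR-184b, known from the cornea and other epithelia, was lower in muscle than in skin (-4.11 ± 0.26). miR-1788-3p differed by -2.98 ± 0.33 between gills and skin and -7.93 ± 0.48 between gills and muscle. miR-129, a neuronal miRNA, was higher in muscle than in gills (4.97 ± 0.25) and skin (3.49 ± 0.23). miR-100 was higher in muscle than in gills by 1.67, which turned to -1.78 with totals only. In muscle the low-abundance names miR-196b-5p (2.20 ± 0.27, edgeR adjusted p = 4.3e-05) and miR-7 (2.06 ± 0.46, 0.0047), a neuronal and endocrine miRNA, rose in summer. Their mean CPM in muscle was 5.9 and 1.34. There miR-338 (-0.90 ± 0.24) and miR-214-5p (-0.81 ± 0.21) fell.

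The hypothesis that the seasonal changes were shared by tissues was tested with the Spearman correlation across profiles, which are not independent replicates. It was 0.342 between gills and skin (242 profiles), 0.33 between gills and muscle (206) and 0.45 between skin and muscle (211). Of 100 splits of the fish, 24, 9 and 17 gave a correlation as high (highest other 0.636, 0.484 and 0.694), and of the 64 splits within batch numbers 10, 11 and 10. Chance differences between the fish of the 2 collections could therefore give such values and cannot be excluded.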
